A study of Mus musculus with 12 samples.

How the data were processed

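RNA of 12 mouse lung tumour samples was measured on 1-colour Illumina bead arrays, with 4 samples each of tumours with mutant K-ras on, 24 h and 48 h after K-RAS inactivation. Per the file headers, the deposited scanner table holds for each probe and array a signal intensity on a linear scale and a detection p-value. The deposited intensity values were neither background-subtracted nor normalised between arrays: no value was below 26.0 and the array medians ran from 49.0 to 55.8. The deposited detection p-value moved in steps of 1 in 936, the number of negative controls this implies. The deposited series table holds log2 values with equal quartiles on every array. Undoing the log2 of each of its values gives a number within 0.001 hundredths of a whole number of hundredths. On bright probes, taken relative to each probe's mean over the arrays, these numbers correlated at 0.987 to 0.998 with the log2 scanner signal of the same array, so log2 had been taken 2 times (median 2.08 as deposited, 4.23 with the outer log undone). The software behind either table is not given in the sources used here. The scanner table was the main source, and the series table was used as an alternative.

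Array positions in the labels put 6 samples on each of 2 slides. Signals were background-corrected and quantile-normalised on the log2 scale with limma's neqc, with detection p-values standing in for negative controls and an offset of 16. Probes were kept when their detection p was under 0.01 on at least 4 of the 12 arrays, which 18314 of 45281 did. A single gene symbol was given for 34885 probes and several for 18, and 10378 probes were unnamed here. Per gene the probe with the highest mean was used, giving 10276 genes, of which 3807 had more than 1 detected probe. Fold changes against a group without detected signal are given as bounds, computed against the level of the lowest detectable signal. Where a gene was detected on a part of a group's arrays, the difference of its means is given, with some of its values near background. The arrays measured between 17014 and 17782 detected probes per sample.

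All 12 samples were fitted in 1 linear model of 3 group means with limma (lmFit and eBayes, 9 residual degrees of freedom). The 3 contrasts were 24 h off minus on, 48 h off minus on, and 48 h off minus 24 h off, the last as the test of a difference between the times. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and the F test asked for any difference across the groups. Values after a gene name are log2 changes in the direction of the contrast, and SE is the moderated standard error. Of 48 gene lists (signalling outputs, metabolic and stress programmes, and markers of lung cell types) fixed before the data were examined, 45 had at least 5 measured genes and were tested with camera at its preset correlation of 0.01, adjusted over lists. The erythroid, mast cell and adipocyte lists, with 4, 4 and 3 measured genes, were not tested. Camera with an estimated correlation and fry were run as alternatives, and members were also adjusted over the list alone. With an estimated correlation no list passed in any comparison, while 6, 3 and 5 lists had an unadjusted p under 0.05. By its directional p, which asks whether the genes of a list move on balance one way, fry called 21, 17 and 15 lists. The report describes 20 of the lists, chosen after the tests were seen. Values of further lists, chosen then too, stand in the closing section, and those of the apoptosis regulators beside their genes.

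Named genes were chosen by a rule fixed before the data were examined: per contrast the 10 largest positive and 10 largest negative log2 changes among called genes whose groups do not overlap, every member of the ERK feedback and output list, the RAS genes, and up to 4 called members of each list with the largest changes. The report's text gives a part of these, 70, 78 and 42 genes, chosen after their values were seen. Predicted and clone-named genes were passed over except BC018473. A part of what this rule names is not reported here.

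Alternatives fixed beforehand were an offset of 50, no background correction, cyclic loess, the series table as deposited, no detection filter and a detection p under 0.05, every probe on its own, the mean of a gene's probes, at least 2-fold changes, fits of the 2 compared groups alone, eBayes with trend and robust settings, array weights, slide as a fixed or random block, fits within a slide, the replicate number as a block, and leaving out each sample in turn. Alternatives added after the data were seen were the series table with its outer log undone, sex read from Xist as a covariate, and the mean of the endothelial and fibroblast lists as a covariate. The median log2 change of all genes stayed within 0.0309 of 0 under every scaling. These scalings make the arrays alike, so a median near 0 is built in and cannot show whether all genes shifted.

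The fit was tested on simulated data, in which 200 genes were raised or lowered in the simulated 24 h samples. The cholesterol synthesis genes were also raised there, by a log2 change of 1. Of the 200 genes, 85 of 100 with a log2 change of 1 and 98 of 100 with a log2 change of 2 were recovered. The genes left unchanged gave 11 false calls. With slide in the fit 45 and 93 were recovered. The correlation of the changes at both times was compared with 100 simulations of unchanged off groups that share the same controls, and the counts with other splits of the samples (all 35 splits for each pair of groups, 100 drawn splits for the 3 groups). Software versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.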

Results

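Gene expression was measured on Illumina bead arrays in lung tumours of mice of an FVB/SV129 strain, aged 19 weeks, that were dissected from the lung and frozen. Each of 12 samples of total RNA was copied into biotin-labelled cRNA for 1 array. The samples formed 3 groups of 4: tumours with mutant K-ras on (time 0), and tumours taken 24 h or 48 h after K-RAS had been inactivated. Every array gave 45281 probe signals, with a median between 49.0 and 55.8 units, and 37.57% to 39.27% of the probes were detected. The number of arrays, 4 per group, limits the precision. The labels do not say that the samples come from separate mice, so the p-values measure the spread between these samples.

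The 4 samples with K-ras on and 2 of the 48 h samples lay on slide 1, while the 4 samples of 24 h and the other 2 of 48 h lay on slide 2. Each comparison is therefore also given with slide in the fit or within a slide. The first 3 principal components carried 32.9%, 29.4% and 8.58% of the variance. Nras, a gene of the RAS family, changed by 0.11 on the log2 scale at 24 h (SE 0.07, limma adjusted p = 0.265) and by 0.07 at 48 h (SE 0.07, adjusted p = 0.491).

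**Figure D1:**
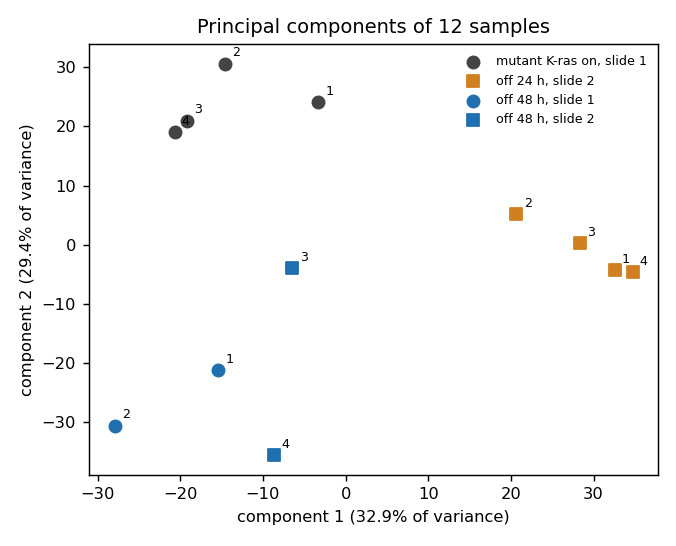
Principal components 1 and 2 of the 12 samples (percent of variance on each axis), computed from the log2 signals of the genes tested; circles lie on slide 1 and squares on slide 2. The 4 samples of 24 h lie above 20 on component 1, and off_48h replicate 3 lies at -4.00 on component 2, apart from the other samples of 48 h, which lie at -21.15 or lower.

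The first comparison asked which genes had changed 24 h after K-RAS inactivation. Of 15 measured transcription factors, feedback inhibitors and other genes that ERK, the kinase below RAS, is known to induce, 11 were lower than in tumours with K-ras on. Etv4, an ETS-family factor, was 5.12-fold lower (log2 change -2.36, SE 0.39, 4 samples per group), and Dusp4, a phosphatase that inactivates ERK, was 3.22-fold lower (-1.69, SE 0.36). Lower were also 9 of 14 genes of glycolysis and 13 of 19 of ribosome production, while 16 of 20 endothelial, 11 of 20 fibroblast and 9 of 14 alveolar type 1 markers were higher, with 1 of the last lower. These 6 lists passed with camera (adjusted p at most 0.00331) but not with an estimated correlation (camera, adjusted p = 0.344 to 0.435). Hopx, a homeobox gene of alveolar type 1 cells, was 3.17-fold higher (1.66, SE 0.16), and Mfap4, a microfibril protein of lung fibroblasts, was 8.71-fold higher (3.12, SE 0.32).

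In all, 3032 of 10276 genes changed at 24 h (limma, adjusted p under 0.05), of which 1526 rose and 1506 fell. A change of at least 2-fold was seen for 511 of them, 323 higher and 188 lower. The 4 samples of each group did not overlap for 3292 of the genes tested, where chance gives 2.86% of them. A fit with slide left 161 genes past the threshold, 98 of them higher, while 1 gene passed for slide itself. With slide as a random block 2853 passed, at a correlation of 0.0144 within slides. In the fixed fit the slide term, and with it the 24 h difference, rests on the 48 h samples, the only group on both slides. Neither the 1 gene nor the low correlation can therefore show that slide had no effect. With the mean of the endothelial and fibroblast markers as a covariate, a fit added after the data were seen, 3 genes passed. That mean itself rose by 0.975 (SE 0.144) at 24 h. The fit thus takes out much of the group difference, and that of its own 2 lists by construction. In that fit the lists of secreted factors, glycolysis, hypoxia, dedifferentiated epithelium, alveolar type 1 cells, endothelium, fibroblasts, matrix, macrophages and interferon response described below did not pass, while those of ERK genes, ribosome production and mitosis did. Among the named genes Ccnd1, Spred1, Plau, Tpi1, Sox9, Cldn2, Inmt, Tcf21, Ear10 and Hba-a1 took the other sign without passing.

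Of the 15 measured members of the ERK feedback and output list, 11 fell (11 adjusted over the list alone), with a median log2 change of -1.09 (camera, adjusted p = 5.68e-05, adjusted p = 0.42 with an estimated correlation). They included Epha2, a receptor tyrosine kinase, at -1.65, Egr1, an immediate early zinc finger gene, at -1.66, the phosphatase Dusp6 at -1.25, and Ccnd1, which encodes cyclin D1, at -0.68. The RAS pathway inhibitors Spry4 and Spred1 changed by -1.10 and -0.57, Spred2 was at least 1.69-fold lower, and Phlda1 and Ier3 changed by -1.18 and -0.84. The 4 members that did not pass were Etv1 (-0.66), Dusp5 (-0.45), Etv5 (-0.05) and Emp1 (0.12). The median of the list was -1.45 with slide in the fit (camera, adjusted p = 6.21e-09). The slide term rests on the 48 h samples, whose mean list values were -1.33 and -1.25 on slide 1. On slide 2 they were -0.474 in off_48h replicate 3 and -1.286 in replicate 4. The larger fall with slide in the fit thus rests on off_48h replicate 3 and does not show a stronger response. The limma calls of Phlda1, Ier3 and Spred1 depended on single samples: Phlda1 lost its call without any 1 of time 0 replicates 2 and 3 and off_24h replicates 3 and 4 (adjusted p up to 0.0618), Ier3 without time 0 replicate 2 or 3 or any of the 24 h samples (up to 0.105), and Spred1 without time 0 replicate 1 or 4 or off_24h replicate 1, 3 or 4 (up to 0.0751).

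Of the secreted factors linked to RAS signalling 5 of 11 fell (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.42 with an estimated correlation). The neutrophil chemokine Cxcl1 was 7.54-fold lower (-2.91, SE 0.27), Hbegf, a ligand of the EGF receptor, was 2.83-fold lower, Plau, the urokinase protease, changed by -1.20, and the cytokine Lif was at least 2.63-fold lower. In the glycolysis list 9 of 14 fell (9 adjusted over the list alone, camera adjusted p = 0.00331, adjusted p = 0.435 with an estimated correlation), among them the glucose transporter Slc2a1 (-1.16), the phosphofructokinase Pfkl (-0.96) and lactate dehydrogenase Ldha (-0.93). The isomerase Tpi1 fell by 0.87 on the probe used, while its other probes gave 0.00 and -0.63. In the hypoxia list 6 of 13 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.0300, adjusted p = 0.42 with an estimated correlation), with Egln3, an oxygen sensor, at -2.18 and Ankrd37 at -1.48. That list no longer passed without time 0 replicate 1 (camera, adjusted p = 0.0502) or time 0 replicate 3 (adjusted p = 0.0558).

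Genes of ribosome biogenesis and MYC targets fell in 13 of 19 cases (15 adjusted over the list alone, camera adjusted p = 7.00e-06, adjusted p = 0.344 with an estimated correlation). Nop58, a nucleolar protein, changed by -1.04, the pyrimidine enzyme Cad by -0.84, and the polyamine enzymes Odc1 and Srm by -0.83 and -0.67. Markers of embryonic, gastric and dedifferentiated epithelium fell in 9 of 18 cases (9 adjusted over the list alone, with 1 other member higher, camera adjusted p = 0.000816, adjusted p = 0.42 with an estimated correlation). The keratins Krt19 and Krt18 changed by -1.40 and -1.16, the progenitor factor Sox9 by -2.40 and the tight junction gene Cldn2 by -1.71. Without off_24h replicate 1 neither Sox9 (limma, adjusted p = 0.0506) nor Cldn2 (0.0535) passed, and Cldn2 did not pass without time 0 replicate 2.

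Endothelial markers rose in 16 of 20 cases (17 adjusted over the list alone, camera adjusted p = 1.34e-08, adjusted p = 0.344 with an estimated correlation). Examples were Lyve1, a hyaluronan receptor (1.94), the angiopoietin receptor Tek (1.54), Ramp2 (1.52) and the endothelial claudin Cldn5 (1.47). Fibroblast markers rose in 11 of 20 cases (13 adjusted over the list alone, camera adjusted p = 1.61e-05, adjusted p = 0.42 with an estimated correlation), led by Mfap4, the methyltransferase Inmt (2.24) and the transcription factor Tcf21 (2.06). Matrix genes rose in 12 of 19 cases (17 adjusted over the list alone, camera adjusted p = 1.82e-06, adjusted p = 0.344 with an estimated correlation), among them the collagen Col3a1 (1.86) and the protease Mmp2 (1.95). Alveolar type 1 markers rose in 9 of 14 cases and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 4.53e-05, adjusted p = 0.344 with an estimated correlation), including Cav1, the coat protein of caveolae (1.74), and Rtkn2 (1.60). The medians of these 4 lists were 0.99, 0.77, 0.74 and 0.87, and with slide in the fit 0.82, 0.55, 0.39 and 0.92, each still past the threshold of camera.

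In the alveolar macrophage list 5 of 13 rose (7 adjusted over the list alone, camera adjusted p = 0.000816, adjusted p = 0.42 with an estimated correlation), with the ribonuclease gene Ear10 at 3.81. Ear10 changed by 4.78 without time 0 replicate 1 and by 4.45 without off_24h replicate 3. In the monocyte and interstitial macrophage list 7 of 16 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.000816, adjusted p = 0.435 with an estimated correlation), with Adgre1, which encodes a macrophage surface receptor, at 1.36. With slide in the fit neither list passed (camera, adjusted p = 0.485 and 0.317, medians 0.22 and 0.20). Mitotic genes rose in 7 of 16 cases (8 adjusted over the list alone, camera adjusted p = 0.000932, adjusted p = 0.42 with an estimated correlation): Cdk1, the mitotic kinase, changed by 0.67, the passenger protein gene Birc5 by 0.64, the checkpoint gene Mad2l1 by 0.56 and the spindle gene Nusap1 by 0.58, the last not passing without off_24h replicate 1 (limma, adjusted p = 0.0507). Interferon response genes rose in 6 of 14 cases (9 adjusted over the list alone, camera adjusted p = 0.000816, adjusted p = 0.42 with an estimated correlation), with Ifit2 2.83-fold higher and Ifit3 at 1.39.

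A large change was that of Prm1, which encodes the sperm chromatin protein protamine 1. Its log2 signal was 12.84 ± 0.26 (SD, n = 4) with K-ras on and 6.69 ± 0.36 (SD, n = 4) at 24 h, 71.1-fold lower. Other large falls were those of Ivl, which encodes the cornified envelope protein involucrin (-3.80), the Golgi mannosidase gene Manea (-3.52), the costimulatory ligand gene Tnfsf9 (-2.66), the somatostatin receptor gene Sstr2 (-2.47), Slc23a3 (-2.42) and Ly6g6c (-2.39), and Prss22 was at least 3.44-fold lower. On the other side BC018473 was at least 21.0-fold higher, the mesothelial gene Upk3b at least 3.63-fold higher, and Ogn, a matrix proteoglycan gene (3.50), Tmem100 (3.33), Pcolce2 (2.69), the myeloid receptor gene Sirpb1a (2.62), the prostaglandin dehydrogenase gene Hpgd (2.60), the cytokine receptor gene Il6st (2.51) and the lipid transfer gene Pltp (2.44) rose. The survival gene Bcl2l1 changed by -1.28 and Mcl1, of the same family, by 0.35. The list of apoptosis regulators did not pass (camera, adjusted p = 0.897), with 3 of 17 measured genes higher and 1 lower. The call of Mcl1 ended in 8 of the 12 fits that each left out 1 sample, those without time 0 replicate 1, 2 or 3, off_48h replicate 1 or 2, or off_24h replicate 1, 2 or 4 (limma, adjusted p up to 0.124). The neutrophil gene S100a8 (2.38) and the globin gene Hba-a1 (1.88) rose.

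The other lists given above as past camera's threshold at 24 h passed with slide in the fit too (camera, adjusted p at most 0.0134). In all, 16 lists passed in either fit, while the genes went from 3032 to 161. Fry and an estimated correlation were not run with slide in the fit. Of the 70 genes named for this comparison, 19 kept their call with slide in the fit and none reversed. The 19 were Prm1, Ivl, Manea, Cxcl1, Slc23a3, Ly6g6c, BC018473, Tmem100, Mfap4, Upk3b, Epha2, Hbegf, Ldha, Nop58, Krt19, Cldn5, Hopx, Ifit2 and Ifit3.

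**Figure D2:**
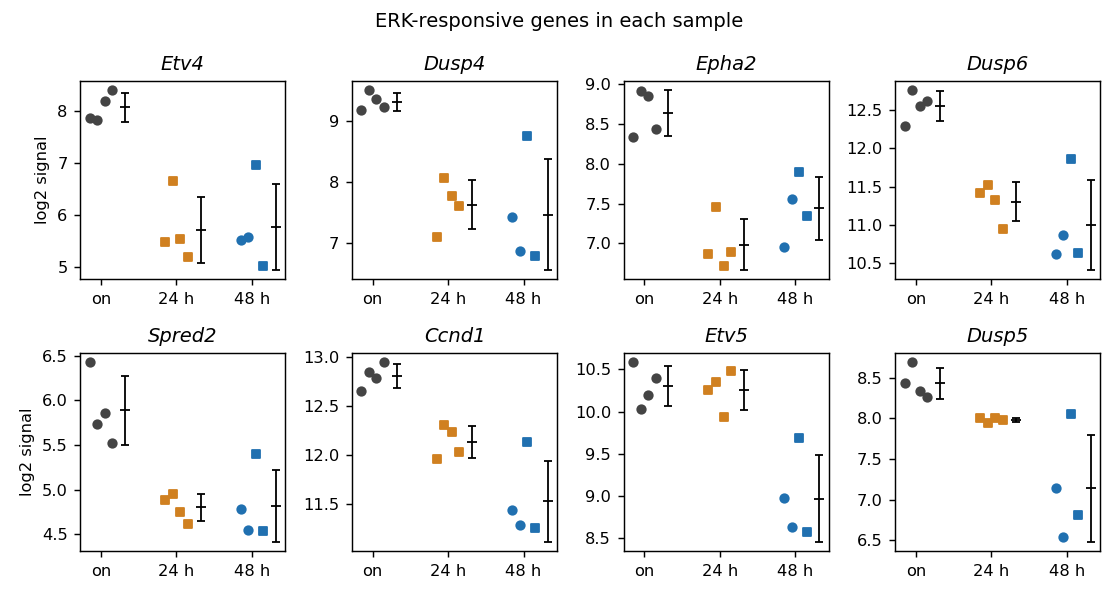
Log2 signal of 8 genes of the ERK feedback and output list in each sample of the 3 groups (circles slide 1, squares slide 2; bars show the mean ± SD of 4 samples). Etv4 has a mean of 8.06 with K-ras on, 5.71 at 24 h and 5.77 at 48 h, while Etv5 has 10.30, 10.26 and 8.97.

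The second comparison asked which genes differed from the tumours with K-ras on at 48 h. Of the 15 ERK genes 12 were lower, with Etv4 4.92-fold lower (-2.30, SE 0.39, 4 samples per group) and Etv5, a related ETS factor, 2.53-fold lower (-1.34, SE 0.23). Lower were also 8 of 16 mitotic genes and 10 of 13 of cholesterol synthesis: the mitotic kinase gene Cdk1 was 1.53-fold lower (-0.61, SE 0.16), and Fdps, an enzyme of the mevalonate pathway, 2.30-fold lower (-1.20, SE 0.17). Of the markers of ciliated airway cells 4 of 12 were higher, of clock genes 7 of 12 and of glucocorticoid-responsive genes 10 of 16, with 1 clock and 1 glucocorticoid gene lower. The clock gene Per1 was 2.47-fold higher (1.30, SE 0.22). These 6 lists passed with camera (adjusted p at most 0.00676) but not with an estimated correlation (camera, adjusted p = 0.249 to 0.593).

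In all, 2825 genes changed at 48 h (limma), 1423 of them higher and 1402 lower, and 372 changed by at least 2-fold, 170 higher and 202 lower. The groups did not overlap for 27.2% of the genes, where chance gives 2.86%. A fit with slide gave 2271 genes, 1175 of them higher, and within slide 1, with 2 samples of 48 h, 1914 passed, 998 of them higher. With the mean of the endothelial and fibroblast markers as a covariate 1012 passed, 570 of them higher, and the endothelial, fibroblast, matrix, interferon and ciliated lists described below did not pass.

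In the ERK feedback and output list 12 of 15 fell (12 adjusted over the list alone), with a median of -1.20 (camera, adjusted p = 7.74e-06, adjusted p = 0.362 with an estimated correlation) and of -1.38 within slide 1. Dusp4 changed by -1.86, Dusp6 by -1.55, Phlda1 by -1.36, Dusp5 by -1.30, Ccnd1 by -1.29, Epha2 by -1.20, Spred2 by -1.07 (detected in 1 of the 4 samples of 48 h), Ier3 by -0.95, Spry4 by -0.72 and Spred1 by -0.52. Etv1 (-0.61), Egr1 (-0.24) and Emp1 (0.03) did not pass. Ier3 lost its limma call without time 0 replicate 2 or 3 or off_48h replicate 1 or 4 (adjusted p up to 0.0713), Spry4 without time 0 replicate 2 or 3 or off_48h replicate 2 (up to 0.0539). Spred1 lost it in 9 of the 12 fits, keeping it without off_48h replicate 3 or off_24h replicate 2 or 4 (up to 0.118).

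Secreted factors fell in 7 of 11 cases and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.362 with an estimated correlation): Cxcl1 changed by -2.45, Hbegf by -2.22 and Plau by -1.79, and Epgn, another EGF receptor ligand, was at least 3.24-fold lower. Glycolysis genes fell in 10 of 14 cases (11 adjusted over the list alone, with 1 higher, camera adjusted p = 1.77e-05, adjusted p = 0.362 with an estimated correlation), with Pgk1 at -1.14, Ldha at -1.07, Slc2a1 at -1.06 and Gapdh at -1.0. The hypoxia list did not pass (camera, adjusted p = 0.0677; 0.0207 without time 0 replicate 4), with 5 of 13 lower and 2 higher (6 and 2 adjusted over the list alone). Genes of ribosome biogenesis and MYC targets fell in 12 of 19 cases (12 adjusted over the list alone, camera adjusted p = 1.77e-05, adjusted p = 0.249 with an estimated correlation), with Srm at -1.09, Cad at -0.84 and the small nucleolar ribonucleoprotein gene Nhp2 at -0.84.

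Cholesterol synthesis genes fell in 10 of 13 cases (10 adjusted over the list alone, camera adjusted p = 0.000140, adjusted p = 0.362 with an estimated correlation). Besides Fdps, the sterol enzymes Msmo1 and Lss changed by -1.0 and -0.77, and the lipid transfer gene Stard4 by -0.75. DNA replication genes fell in 7 of 23 cases (7 adjusted over the list alone, camera adjusted p = 0.000204, adjusted p = 0.565 with an estimated correlation), with the helicase subunits Mcm2, Mcm3 and Mcm5 at -0.92, -0.91 and -0.67 and thymidine kinase Tk1 at -0.90. Mitotic genes fell in 8 of 16 cases (10 adjusted over the list alone, camera adjusted p = 0.00291, adjusted p = 0.534 with an estimated correlation), among them Cdc20, an activator of the anaphase-promoting complex (-0.62), and the spindle gene Prc1 (-0.55). Stard4 lost its limma call without time 0 replicate 1 or 4 or off_48h replicate 2 or 4 (adjusted p up to 0.0636), Mcm5 without time 0 replicate 1 or 4 or off_48h replicate 1 or 4 (up to 0.0624), and Prc1 without time 0 replicate 1 or off_48h replicate 4 (up to 0.0509).

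Ciliated cell markers rose in 4 of 12 cases (8 adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.593 with an estimated correlation). The list did not pass with fry (adjusted p = 0.0532). The dynein light chain gene Dynlrb2 changed by 1.67, Ccdc113 by 1.38 and the dynein intermediate chain gene Dnaic1 by 1.27, and Enkur was at least 2.07-fold higher. Ccdc113 lost its limma call without time 0 replicate 2 or 4 or off_48h replicate 2 or 4 (adjusted p up to 0.0581), and Dnaic1 in 7 of the 12 fits, those without time 0 replicate 1, 2 or 4, off_48h replicate 2 or 4 or off_24h replicate 1 or 2 (up to 0.107). Club cell markers, of the same airways, rose in 3 of 13 cases with a median of 0.98, and the list did not pass (camera, adjusted p = 0.0542). It passed within slide 1 (0.0122) and without time 0 replicate 3 or off_48h replicate 1 or 3 (camera, adjusted p down to 0.00574). The scores of off_48h replicate 3 were the lowest of the 48 h samples in the ciliated and the club cell list, at 0.10 and -0.43. Glucocorticoid-responsive genes rose in 10 of 16 cases and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.00326, adjusted p = 0.362 with an estimated correlation), with the zinc finger gene Zbtb16 at 1.57 and Pdk4, a kinase that restrains pyruvate oxidation, at 1.44. Zbtb16 lost its limma call without time 0 replicate 2 or 3 or off_48h replicate 2 (adjusted p up to 0.0790). Clock genes rose in 7 of 12 cases and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00676, adjusted p = 0.249 with an estimated correlation), with Per1, Per3 (1.09), Cry2 (1.00) and Tef (0.96).

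Endothelial markers were higher at 48 h in 12 of 20 cases and lower in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.000563, adjusted p = 0.536 with an estimated correlation), with Lyve1 at 1.30 and the transcription factor Sox18 at 1.12. Alveolar type 1 markers rose in 8 of 14 cases (10 adjusted over the list alone, camera adjusted p = 0.000452, adjusted p = 0.362 with an estimated correlation), with Hopx at 1.39 and Rtkn2 at 1.31. Interferon response genes rose in 4 of 14 cases (4 adjusted over the list alone, camera adjusted p = 0.00702, adjusted p = 0.583 with an estimated correlation). Fibroblast markers rose in 4 of 20 cases and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0378, adjusted p = 0.612 with an estimated correlation), and matrix genes rose in 5 of 19 cases and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0180, adjusted p = 0.593 with an estimated correlation). Within slide 1 neither the fibroblast nor the matrix list passed (camera, adjusted p = 0.125 for both), and neither passed without time 0 replicate 4 (0.168 and 0.0955) or off_48h replicate 4 (0.221 and 0.110). With fry neither passed in all samples (adjusted p = 0.103 and 0.0532). Macrophage markers gave medians of -0.28 (alveolar macrophage, camera adjusted p = 0.120) and 0.08 (monocyte and interstitial macrophage; adjusted p = 0.743). The alveolar macrophage list passed as lower within slide 1 (camera, adjusted p = 0.00639) and without off_48h replicate 3 (0.0448). The other lists given for 48 h as past camera's threshold passed within slide 1 too (camera, adjusted p at most 0.0224). Fry and an estimated correlation were not run within slide 1.

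Dedifferentiated epithelial markers fell in 10 of 18 cases and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.00184, adjusted p = 0.534 with an estimated correlation), with Krt19 at -1.84, the differentiation inhibitor Id2 at -1.60 and Sox9 at -1.96. Sox9 lost its limma call in 7 of the 12 fits, those without time 0 replicate 2, 3 or 4, off_48h replicate 1, 2 or 4 or off_24h replicate 3 (adjusted p up to 0.107). Among alveolar type 2 cell genes, Lamp3, of the lamellar body membrane, changed by -1.73 and the lung chemokine gene Cxcl15 by -1.55, while the complement gene Hc rose (0.92). Of the BCL2 family, the proapoptotic genes Bik and Bcl2l11 rose (1.03 and 0.64), the survival gene Mcl1 rose (0.68) and Bcl2l1 fell (-1.02). Bcl2l15, given below, fell too. The list of apoptosis regulators did not pass (camera, adjusted p = 0.220), with 5 of 17 measured genes higher and 3 lower.

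Prm1 was 37.7-fold lower at 48 h (log2 7.60 ± 0.45, SD, n = 4), and Ivl (-4.51), Manea (-2.94) and Tnfsf9 (-2.64) were again among the largest falls. Without off_48h replicate 3 Ivl changed by -5.18 and Tnfsf9 by -3.31. Others were the mast cell tryptase gene Tpsab1 (-3.75), the lysolipid transporter gene Mfsd2a (-3.67), Bcl2l15 (-3.11), the proprotein convertase gene Pcsk6 (-2.64), the glycosyltransferase gene B3gnt7 (-2.55) and the transcription factor gene Sp5 (-2.48). Among genes whose groups do not overlap, the largest rises were those of the brain proteoglycan gene Bcan (2.23), the TNF receptor adaptor gene Traf1 (2.22, SE 0.12), the amylase gene Amy2a5 (1.88), the WNT inhibitor gene Notum (1.86), Snhg11 (1.86), Vpreb3 (1.83), the deubiquitinase gene Usp2 (1.83), Fam184a (1.82, while its other probes gave 1.33 and -0.01), the carbonyl reductase gene Cbr2 of club cells (1.80) and Rasl12 (1.78). Of the 78 genes named for this comparison, 69 kept their call with slide in the fit, and 68 within slide 1. The 9 that lost it with slide in the fit were Ier3, Spred1, Cdk1, Lyve1, Dnaic1, Mcm5, Prc1, Stard4 and Sox9 (limma, adjusted p from 0.0514 to 0.121), and their direction stayed the same.

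**Figure D3:**
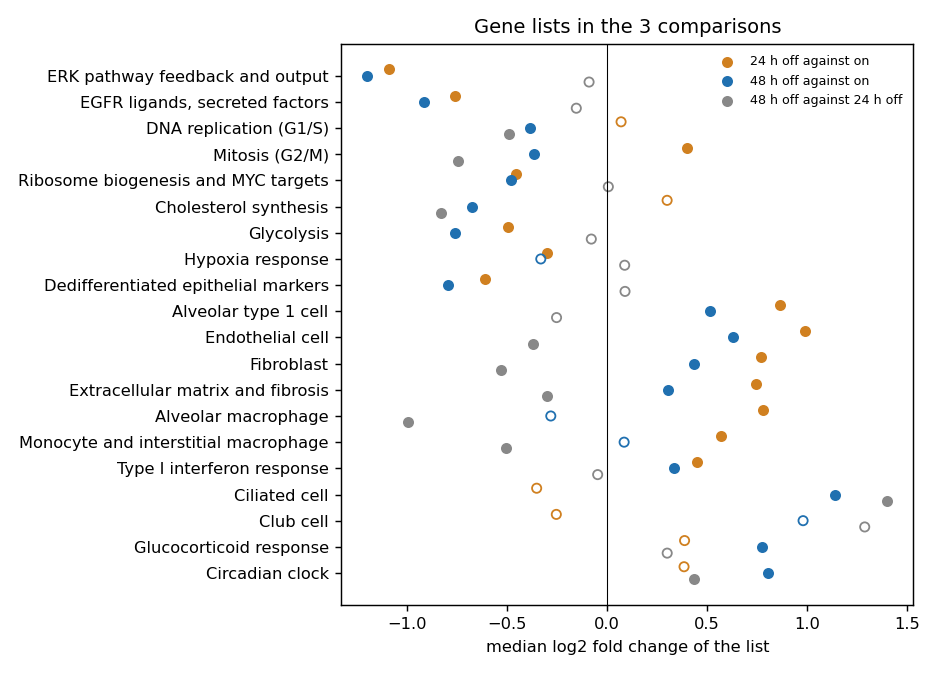
Median log2 fold change of 20 gene lists (x axis) in the 3 comparisons, with filled points for lists past camera's threshold with its preset correlation and open points for the others. The ERK list lies at -1.09 and -1.20 against K-ras on and at -0.09 between the times, and the mitosis list at 0.40, -0.37 and -0.75.

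The third comparison asked how the response at 48 h differed from that at 24 h. Lower at 48 h were 14 of 16 mitotic genes and 10 of 13 of cholesterol synthesis: Cdk1 was 2.44-fold lower (log2 change -1.29, SE 0.16, 4 samples per group) and Fdps 2.91-fold lower (-1.54, SE 0.17). Of the alveolar macrophage markers 10 of 13 were lower at 48 h than at 24 h, of monocyte and interstitial macrophage markers 8 of 16, of fibroblast markers 10 of 20 and of endothelial markers 8 of 20, with Tcf21, a fibroblast transcription factor, 5.16-fold lower (-2.37, SE 0.36). Of the ciliated cell markers 9 of 12 were higher, with Tekt1, of the ciliary microtubules, 3.86-fold higher (1.95, SE 0.44). These 7 lists passed with camera (adjusted p at most 0.0159) but not with an estimated correlation (camera, adjusted p = 0.358 to 0.650).

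In all, 3081 genes differed between the times (limma), 1542 higher and 1539 lower at 48 h, and 413 differed by at least 2-fold, 152 higher and 261 lower. The groups did not overlap for 28.8% of the genes, where chance gives 2.86%. A fit with slide gave 809 genes, 318 of them higher, and within slide 2, with 2 samples of 48 h, 319 passed, 105 of them higher. With the mean of the endothelial and fibroblast markers as a covariate 240 passed, 108 of them higher, and the endothelial, fibroblast and matrix lists described below did not pass. Across the 3 groups 4970 genes passed limma's F test.

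Mitotic genes were lower at 48 h in 14 of 16 cases (14 adjusted over the list alone, camera adjusted p = 7.29e-08, adjusted p = 0.358 with an estimated correlation), with Mad2l1 at -0.94 and Birc5 at -0.91. DNA replication genes were lower in 13 of 23 cases (16 adjusted over the list alone, camera adjusted p = 1.92e-05, adjusted p = 0.646 with an estimated correlation): Mcm6 changed by -0.88, thymidylate synthase Tyms by -0.81, Mcm3 by -0.79 and the replication gene Gins2 by -0.79. Mcm6 lost its limma call without off_48h replicate 1 or off_24h replicate 1 or 3 (adjusted p up to 0.0545). Cholesterol synthesis genes were lower in 10 of 13 cases (11 adjusted over the list alone, camera adjusted p = 1.42e-06, adjusted p = 0.358 with an estimated correlation), with the sterol enzymes Nsdhl and Msmo1 at -1.17 and -1.10 and Stard4 at -1.05. Within slide 2 the medians of these 3 lists were -0.71, -0.51 and -0.82, beside -0.75, -0.49 and -0.83 in all samples.

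In the ERK list 3 of 15 were lower at 48 h than at 24 h and 1 was higher (3 and 1 adjusted over the list alone, camera adjusted p = 0.599). Etv5 changed by -1.29, Dusp5 by -0.85, Ccnd1 by -0.61 and Egr1 by 1.42. Ccnd1 lost its limma call without off_48h replicate 1, 2 or 4 or off_24h replicate 2 or 3 (adjusted p up to 0.0680). Dusp5 lost its limma call without off_48h replicate 1, 2 or 4 or off_24h replicate 1 or 3 (adjusted p up to 0.0713), and Egr1 without off_48h replicate 2 or 4 or any of the 24 h samples (up to 0.101). Without off_48h replicate 3 the list passed as lower at 48 h (camera, adjusted p = 0.0322). Hbegf changed by -0.72 and lost its limma call without off_48h replicate 1, 2 or 4 or any of the 24 h samples (adjusted p up to 0.126). The lists of secreted factors (camera, adjusted p = 0.450), ribosome biogenesis (0.724), glycolysis (0.151), hypoxia (0.677), dedifferentiated epithelium (0.963), alveolar type 1 cells (0.210), interferon response (0.450) and glucocorticoid response (0.146) did not pass between the times. The glucocorticoid list passed without off_48h replicate 3 (camera, adjusted p = 0.0322) and the glycolysis list without off_24h replicate 4 (0.0473).

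Alveolar macrophage markers were lower at 48 h in 10 of 13 cases (12 adjusted over the list alone, camera adjusted p = 4.53e-06, adjusted p = 0.411 with an estimated correlation), with Ear10 at -4.09. Without off_48h replicate 4 it changed by -4.70, and without off_24h replicate 3 by -4.73. Monocyte and interstitial macrophage markers were lower in 8 of 16 cases (8 adjusted over the list alone, camera adjusted p = 0.000199, adjusted p = 0.646 with an estimated correlation). Fibroblast markers were lower in 10 of 20 cases (10 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.650 with an estimated correlation), with Mfap4 at -2.10. Endothelial markers were lower in 8 of 20 cases (8 adjusted over the list alone, camera adjusted p = 0.00745, adjusted p = 0.650 with an estimated correlation) and matrix genes in 7 of 19 cases (8 adjusted over the list alone, camera adjusted p = 0.00320, adjusted p = 0.646 with an estimated correlation). The fibroblast list did not pass without off_48h replicate 3 (camera, adjusted p = 0.0846), nor the endothelial list without off_24h replicate 4 (0.0519). With fry neither of these 2 lists passed in all samples (adjusted p = 0.0557 and 0.0577).

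Ciliated cell markers were higher at 48 h in 9 of 12 cases (11 adjusted over the list alone, camera adjusted p = 0.000350, adjusted p = 0.650 with an estimated correlation), with the cadherin gene Cdhr3 at 2.14. The rise was uneven: the list scores were 1.73 and 1.82 in off_48h replicates 2 and 4 and 0.78 and 0.10 in replicates 1 and 3. Clock genes were higher in 4 of 12 cases (6 adjusted over the list alone, camera adjusted p = 0.0480, adjusted p = 0.358 with an estimated correlation), with Per1 at 0.93 and Cry2 at 0.82. The clock list did not pass without off_48h replicate 4 or off_24h replicate 1, 2 or 3 (camera, adjusted p up to 0.0815). Club cell markers were higher in 3 of 13 cases, with a median of 1.29, and the list did not pass (camera, adjusted p = 0.0574; 0.165 within slide 2). It passed without time 0 replicate 2 or 3, off_48h replicate 1 or 3 or off_24h replicate 4 (camera, adjusted p down to 0.00843). The lists given above as past camera's threshold between the times also passed within slide 2 (camera, adjusted p at most 0.0306). In all, 17 lists passed there beside 319 genes, and 16 beside 3081 genes in all samples. Camera's list calls thus did not weaken with fewer samples as the gene calls did. Fry and an estimated correlation were not run within slide 2.

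Between the times BC018473 was at least 21.6-fold lower at 48 h, Ear10 17.0-fold lower and Sirpb1a at least 8.50-fold lower. Ear10 was 26.5-fold lower without off_24h replicate 3, and its log2 change was -4.70 without off_48h replicate 4. Other large falls were those of the chitinase-like gene Chil4 (-3.05, or -2.34 without off_48h replicate 2), the chemokine gene Ccl6 (-2.96), Mfsd2a (-2.93), the lipase gene Lipf (-2.92), Tmem100 (-2.84) and the globin genes Hbb-bt (-2.69) and Hba-a1 (-2.63). S100a8 (-2.43), Cxcl15 (-1.67) and Lamp3 (-1.44) were lower too. The heat shock gene Hspa1a (2.74), Kndc1 (2.25), the ciliary genes Rsph4a (2.03) and Cfap65 (2.01) and Amy2a5 (1.99) were higher, Zbtb16 was at least 3.65-fold higher, and the lipid droplet gene Plin4 was at least 3.45-fold higher. Of the 42 genes named for this comparison, 26 kept their call with slide in the fit, and 19 within slide 2. The 16 that lost it with slide in the fit were Ear10, Tekt1, Rsph4a, Cdhr3, Kndc1, Plin4, Zbtb16, Hspa1a, Cxcl15, Per1, Cry2, Egr1, Ccnd1, Dusp5, Hbegf and Mcm6, all with the same direction.

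**Figure D4:**
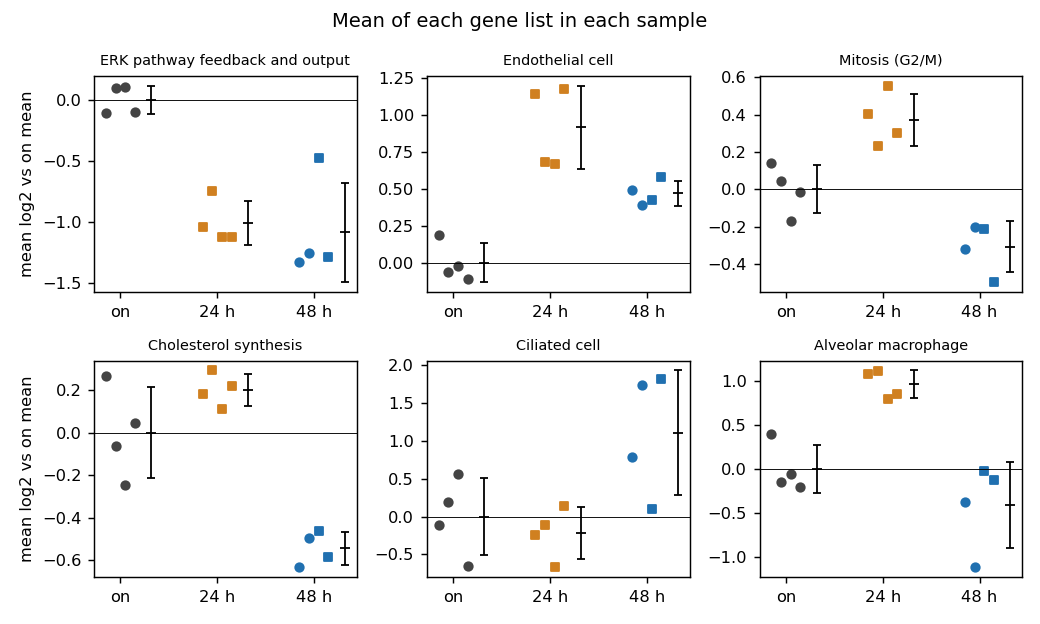
Mean log2 signal of 6 gene lists in each sample, relative to the mean of the samples with K-ras on (circles slide 1, squares slide 2; bars show the mean ± SD of 4 samples). The ERK list lies at -0.47 in off_48h replicate 3 and between -1.33 and -1.25 in the other samples of 48 h.

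The changes at the 2 times were compared gene by gene. Genes such as Etv4, Ivl and Hopx changed at both times in the same direction: 544 genes were higher at both and 649 lower at both, and 62 genes passed in opposite directions. Independent lists of these sizes would share 211.3 higher and 205.5 lower genes, a number that leaves out the shared controls. Cdk1, which rose at 24 h and fell at 48 h, was among the 62. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.486 and a covariance of 0.113. Both comparisons share the 4 samples with K-ras on, and simulated groups without any change gave a mean correlation of 0.5004 (0.445 to 0.560) but a covariance of 0.0203, so the correlation alone does not separate a shared response from shared controls. With the controls split into 2 and 2 samples the mean correlation was 0.384 (0.246 to 0.524) and the mean covariance 0.0945. The changes then share no control sample, so these values argue against shared controls as the only source of the covariance. They say nothing about slide, which the splits leave in place. Slide in the fit gave a correlation of 0.622. In that fit both changes also share the 2 samples of 48 h on slide 1, and unchanged groups were not simulated for it. It cannot be set beside 0.5004, nor read as a stronger shared response.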

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

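The tests of a lower tumour share, of more alveolar tissue and of the slide for the stromal markers, of the slide for Prm1, and of mixing, the slide and the time label for off_48h replicate 3 were chosen after the results were seen.

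Lung endothelial and fibroblast markers were higher at 24 h: the mean of both lists rose by 0.975 (SE 0.144) on the log2 scale. If a lower share of tumour cells raised every other cell type alike, their lists would rise together. The endothelial list rose by 1.139 (SE 0.403) more than the ciliated list, and smooth muscle markers moved by 0.17 (SE 0.149). These values argue against such an even rise only. They cannot decide on a lower tumour share made up by some cell types, such as those of alveolar tissue. With slide in the fit the difference was 0.818 (SE 0.255), which argues against the slide as the whole cause, though weakly. The slide term rests on the 48 h samples alone, 2 on each slide. Their fibroblast scores were 0.20 and 0.28 on slide 1 and 0.06 and 0.92 on slide 2. More alveolar tissue taken with the 24 h tumours stays open: the shifts of the alveolar type 1, endothelial, fibroblast and mesothelial lists (0.85, 0.92, 1.03 and 1.13) spanned 0.284 (SE 0.163), so this may account for them. A change in these cells themselves after K-RAS inactivation stays open too and was not tested apart from it.

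Prm1 fell in every off sample, from at least 12.51 in the on samples to at most 7.90. Of 13 other spermatid genes (20 probes), 0% of the detection calls on the on arrays were positive, which argues against male germ cell RNA, and within slide 1 Prm1 was lower by -4.97 (SE 0.20), which argues against the slide. A candidate explanation is protamine 1 sequence in the inducible K-ras construct, a hypothesis for which 0 other spermatid genes were detected on the on arrays; the construct's sequence was not analysed here.

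ERK genes fell less in off_48h replicate 3, whose list score was -0.474 beside -1.33, -1.25 and -1.29 in the other samples of 48 h. RNA of an on tumour mixed into it would bring Prm1 to 11.67, but Prm1 was 6.94 there, below the others (mean 7.83, SD 0.0781). Genes outside the ERK list that differ between the times without this sample were used to place it. It lay at 0.583 of the way from the 24 h mean to the mean of the other 48 h samples. The other 48 h samples, each left out and placed in the same way, lay at 0.961, 1.18 and 0.750. Their axes thus include off_48h replicate 3 and are not the same as its own. A bound of 0.5, set before, was passed by less than that spread, but the 24 h samples, each held out in turn, lay at 0.0110 to 0.149 (mean 0.0708, SD 0.0584), which argues against a 24 h sample with a wrong label. Its Prm1 level did lie in the range of the 24 h samples (6.35 to 7.11). The other sample of 48 h on slide 2 had a score of -1.286, which argues, from 1 sample, against the slide for the ERK score. In their positions, both 48 h samples on slide 2 (0.583 and 0.750) lay nearer the 24 h samples, all on slide 2. Those on slide 1 lay at 0.961 and 1.18. A part of the slide in these positions was not tested. A weaker or slower response of this tumour stays open, without a test.

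Of 462 groups of 4 samples tested for a sample far from the rest (Dixon's ratio, 5% level), 32 gave one, where chance at 1 in 20 gives 23.1, and 10 of the 32 came from off_48h replicate 3. In that sample they were Amy2a5 (0.955), Cxcl15 (0.939), Ldha (0.890), Nhp2 (0.867), Ly6g6c (0.849), Tnfsf9 (0.848), Fam184a (0.847), Prm1 (0.839), Mad2l1 (0.837) and the ERK list (0.906). In off_48h replicate 4 they were the matrix list (0.972), Col3a1 (0.910), Nusap1 (0.904), the DNA replication list (0.875), Rtkn2 (0.857) and Tpi1 (0.835), and in off_48h replicate 2 Adgre1 (0.841). In the 24 h samples Ccl6 (0.929) and the glucocorticoid list (0.834) stood apart in replicate 1, Pcsk6 (0.898), Spred1 (0.896) and Prss22 (0.860) in replicate 2, Chil4 (0.962) and Ear10 (0.906) in replicate 3, and Id2 (0.846) and Cxcl1 (0.834) in replicate 4. With K-ras on these were Tpsab1 (0.958) and Ear10 (0.918) in replicate 1, the alveolar type 1 list (0.903) and Ly6g6c (0.843) in replicate 2, and Chil4 (0.921) and the monocyte and interstitial macrophage list (0.831) in replicate 4.

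The responses at 24 h and 48 h differed for 3081 genes, and 62 of the genes past the threshold at both times went opposite ways. By camera 16 lists differed, with these medians of 48 h minus 24 h: alveolar macrophage -1.0, neutrophil -0.85, cholesterol synthesis -0.83, mesothelium -0.82, mitosis -0.75, fibroblast -0.53, monocyte and interstitial macrophage -0.51, DNA replication -0.49, complement and coagulation -0.44, MHC class II -0.38, endothelial cell -0.37, extracellular matrix -0.30, fatty acid synthesis -0.15, circadian clock 0.43, heat shock 0.65 and ciliated cell 1.40. With an estimated correlation camera called 0 of them (adjusted p from 0.101 for the neutrophil list to 0.650), and 5 of all lists had an unadjusted p under 0.05. Of all 45 lists fry called 15, and 13 of these were among the 16. Among probes without a gene name here, 665, 556 and 892 passed limma's threshold at 24 h, at 48 h and between the times.

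Other splits of the samples gave fewer genes. The real counts of 3032, 2825 and 3081 genes were reached by 1 of 35 splits each, the real one, and the highest other splits called 1, 22 and 1 genes; across the 3 groups 4970 genes were reached by 1 of 100 drawn splits, the highest other calling 1484. The real split is 1 of 35, or of 100 drawn, so its share cannot be small enough to exclude chance. The other splits also mix the real groups, which widens the spread within them. For 24 h against on the real split is that of the slides too. The numbers of lists past camera's threshold did not stand out. As many as the real 16, 18 and 16 were given by 12, 7 and 11 of 35 splits. The highest other splits gave 21, 26 and 23.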

How the results depend on the processing

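The fits with sex read from Xist, with the stromal covariate and with the outer log of the series table undone were chosen after the data were seen. The counts of genes stayed within 1.5 times of the main ones for the offset, background, loess, series table, detection filter, mean of probes, trend, array weight, 2-group, random slide block, replicate block and sex alternatives (2558 to 4212 at 24 h, 2201 to 3147 at 48 h, 2564 to 3800 between the times). The replicate block gave 2558, 2279 and 2564 genes; the numbers do not pair the samples, whose deviations correlated at -0.318 to 0.212. Leaving out each sample in turn gave 2143 to 3116, 1955 to 3021 and 2056 to 3115 genes, 3993 to 4996 across the groups, 15 to 17, 15 to 20 and 13 to 20 lists, and a correlation of 0.440 to 0.546. Over the named genes, 13 alternatives other than leaving out samples, slide and stromal fits kept the call of 2431 of 2470 values, and 39 were weaker. Every probe on its own gave 4903, 4395, 5589 and, across the groups, 8444, since more items were tested. At least 2-fold changes numbered 511, 372, 413 and 909, a stricter rule. With slide as a fixed block 161, 809 and, across the groups, 2785 genes passed, and within slide 2 there were 319 with fewer samples. The slide fit gave a correlation of 0.622, where both changes also share the 48 h samples of slide 1. With the controls split the correlation was 0.384. With an estimated correlation 0, 0 and 0 lists passed, and the smallest adjusted p of camera was 0.344, 0.249 and 0.101. The size of the correlation is not the only difference from the preset test. For the apoptosis regulators at 48 h the estimate was 0.01, as preset, but camera's unadjusted p went from 0.132 to 0.166. For the neutrophil list between the times it was -0.0298, below the preset, but that p went from 7.2e-05 to 0.00224. With the stromal covariate 3, 1012, 240 and, across the groups, 2353 genes passed. The lists past camera's threshold numbered 15, 13 and 17, of which 4, 3 and 8 were higher, against 10, 9 and 3 without it; of the 20 lists the report describes 10, 4 and 1 no longer passed, 3, 1 and 3 passed newly and 1, 1 and 2 changed direction without passing. There the 24 h changes reversed for Ccnd1 (0.19), Spred1 (0.27), Plau (0.51), Tpi1 (0.10), Sox9 (0.53), Cldn2 (1.35), Inmt (-0.64), Tcf21 (-0.0559), Ear10 (-1.30), Hba-a1 (-0.11) and the fibroblast list (-0.15), and the direction of camera's test for the fibroblast list at 48 h (median 0.15) and for the endothelial and fibroblast lists between the times (0.13 and 0.069). The cause was not tested. Between 37.57% and 39.27% of probes lay above background, which limits what low signals can show.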

Other observations

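The groups in this part were picked after the values were seen. Of 4 measured mast cell genes 2 fell and 1 rose at 48 h. The tryptase gene Tpsab1 changed by -3.75 and Hdc, the histidine decarboxylase that makes histamine, by -1.67 (limma, adjusted p = 0.00785 and 1.90e-05, all 4 samples lower than with K-ras on), while Gata2, a transcription factor of mast and endothelial cells, rose by 1.25 (adjusted p = 0.000524). Neutrophil genes were higher at 24 h in 6 of 14 cases, with S100a8 at 2.38 and S100a9 at 1.89 (limma), yet the list did not pass (camera, adjusted p = 0.0761), and by 48 h they were lower than at 24 h in 7 of 14 cases (camera, adjusted p = 0.000463; adjusted p = 0.101 with an estimated correlation).

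Alveolar type 2 genes went both ways at 48 h: 6 of 19 fell, among them Lamp3 (-1.73) and Cxcl15 (-1.55), and 2 rose, among them the complement gene Hc (0.92), and the list did not pass (camera, adjusted p = 0.391). Genes of the unfolded protein response list fell at 48 h in 7 of 20 cases and 1 rose (camera, adjusted p = 0.0316; adjusted p = 0.362 with an estimated correlation), with calreticulin Calr at -1.26 and the disulphide isomerase Pdia6 at -1.21. Mesothelial genes rose at 24 h in 4 of 5 cases (camera, adjusted p = 0.00331; adjusted p = 0.344 with an estimated correlation), and 3 of the 5 were lower again at 48 h.

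The share of samples with low Xist, a transcript of female cells, differed between the groups. Its log2 signal was 5.15 and 5.48 in time 0 replicates 1 and 4 and 4.2 in off_24h replicate 4, and 10.48 or higher in the other samples. A probe of the Y-linked gene Kdm5d gave 6.94, 6.87 and 6.92 in these 3 samples and at most 4.41 in the others, and a probe of Uty, also Y-linked, gave 5.57, 5.83 and 5.87 against at most 5.35. The other Y-linked probes, of Eif2s3y, Uty and Kdm5d, gave at most 4.71 in every sample. With low Xist as a covariate 2959, 2201 and 2688 genes passed limma's threshold.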
